A study of Mus musculus with 20 samples.

How the data were processed

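RNA-seq was measured in 20 mouse samples: 5 libraries each of sorted WT, sorted IL33KO, bulk WT and bulk IL33KO material from orthotopic KPC tumours. Per the labels' protocols, tumours were made into a single-cell suspension, CD45+ cells were selected on magnetic beads (Miltenyi Biotec), RNA was extracted with the RNeasy Plus Mini kit (Qiagen), and libraries were prepared with a stranded poly(A) kit (TruSeq Stranded mRNA). The submitters' processing notes name Picard, HTSeq and DESeq, without versions, and the mm10 build (GRCm38); the aligner, its settings and the strand setting of the counting are not given in the sources used here. Each group's label and replicate number (1 to 5) came from the sample titles.

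The authors deposited a table of raw HTSeq counts per gene, with no normalization, for all 20 samples. It has 46983 genes and 5 summary lines, which were kept out of library sizes and tests; they held 26.1 to 40.5% of the reads in a library, 12.5 to 22.5% being reads that did not align uniquely and 4.38 to 11.2% reads that did not align. In sorted libraries the share that did not align uniquely was 15.1 to 18.9% in WT (median 16.5%) and 16.5 to 22.5% in those labelled IL33KO (median 19.1%). Whether this bears on the genotype comparison was not tested. The number of unaligned reads (M, mega) was 4.33 M in sorted WT 3 and 4.80 M in bulk IL33KO 1, against 7.68 to 9.29 M in the other 18 libraries. The authors also deposited a second table of scaled signal, the counts divided by DESeq size factors, per the file headers; it has 22924 genes, and the genes it leaves out have at most 14 counts over all libraries. That table was used only as an alternative. Reads that align to several places are not in the counts, so genes with near-identical copies (haemoglobin, trypsin, MHC class I and Ear family genes among them) are uncertain, and overlapping or antisense genes are uncertain because the strand setting is not given.

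Gene symbols came from the count table, and coordinates from GENCODE M21 (GRCm38) by gene identifier without its version, which matched 46488 of the genes. No pair of replicates agreed within sampling noise: the lowest chi-square per gene between replicates was 19.6. The labels do not say that the libraries of a group are separate mice beyond naming 5 hosts per genotype, so p-values measure the spread between these libraries, which may be partly technical. If sorted and bulk libraries share tumours, they are not independent of each other.

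Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. For each compartment the 10 libraries were fitted by genotype after filterByExpr and TMM normalization (factors 0.756 to 1.25 over all 20), with the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest); the interaction and the sorted against bulk comparison used all 20 libraries. Values in CPM use TMM-scaled library sizes, and log2 CPM a prior count of 2. Adjusted p values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. All tests were two-sided. The common biological coefficient of variation was 0.300 in sorted leukocytes and 0.354 in bulk tumour.

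Gene lists, 41 in number with 505 symbols (3 absent from the files), were fixed before the data were examined. They cover leukocyte types, the other cells a pancreatic tumour or a bead selection could hold, response pathways, sex-linked genes and neighbours of Il33. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), and again with the correlation estimated per list, with fry and with an exact permutation test of the list score, the mean log2 CPM of its members, over all 252 assignments of 5 and 5 libraries. Some genes stand in several lists, so the list tests are not independent of each other. Each list was also adjusted over the list alone. That adjustment does not correct for the number of lists, so over the 41 lists single genes can pass it by chance.

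Genes named singly followed a rule fixed in advance: Il33 and Il1rl1 always; the 10 largest changes per direction among genes past the threshold with at least 5 CPM in the higher group, or, where fewer than 5 passed, the 5 smallest p values per direction; the 5 smallest p for the interaction; at most 4 members per list by smallest p; and Ccl5, Itgae, Batf3, Cd8a, Ifng, Gzmb, Foxp3, Cd274, Pdcd1, Il5, Il13, Gata3 and Areg. Predicted gene models, pseudogenes and immunoglobulin or T cell receptor segments were counted but not named singly, save where stated. The result of 1 list member is not reported here.

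The tests were first run on simulated data, with counts drawn at the real means, library sizes and dispersions. Known changes were put into some of the genes with a mean of at least 5 CPM, so recovery of lower genes was not measured. EdgeR recovered 17.9% of the genes changed 1.5-fold, 68.7% of those changed 2-fold and 100% of those changed 4-fold in the sorted comparison, with 8 unchanged genes called; in bulk tumour it recovered 16.4%, 64.2% and 100%, with 3. For the interaction the shares were 10.4%, 47.8% and 92.4%, with 5 unchanged genes called, and for sorted against bulk 73.1%, 92.5% and 97.0%, with 4. DESeq2 1.42.0 recovered more, 38.8%, 80.6% and 100% in sorted leukocytes, and called 40 unchanged genes among 186 calls there and 46 among 190 in bulk tumour. Camera, run on 40 simulated lists of independent genes, found the 1 changed list in both compartments and called 0 others. In the real lists the median estimated correlation was 0.359 in sorted leukocytes and 0.531 in bulk tumour. The simulation therefore does not show how often camera with the preset correlation calls real lists by chance.

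Alternatives tried were DESeq2 size factors, the DESeq2 Wald test, no filter and a filter of 5 CPM in 5 libraries, the replicate number as a block, one fit of all 20 libraries, limma voom with sample quality weights, the acinar or the pan-leukocyte score as a covariate, limma-trend on log2 of the authors' scaled signal with a pseudocount of 1, and leaving out each library in turn. Regroupings of the samples were drawn 100 times with edgeR, voom and camera and 60 times with DESeq2.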

Results

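The data set held 20 RNA-seq libraries from KPC pancreatic tumours, a mouse tumour model. The tumours had been grown from cultured KPC cells placed orthotopically in the pancreas of wild-type (WT) or IL33-/- mice on the C57BL/6 background and taken at 2 weeks. IL-33 is an alarmin cytokine that signals through the receptor ST2, encoded by Il1rl1. From tumours of each host genotype there were 5 libraries of CD45+ tumour-infiltrating leukocytes, enriched with magnetic beads, and 5 libraries of bulk tumour. Each library held 51.3 to 81.0 M counts in genes (median 59.5 M; M stands for mega), with 21158 to 23126 genes detected. A value of 3 counts corresponded to 0.0331 to 0.0676 CPM, the counts scaled to library size. The labels name 5 host mice per genotype but do not tie single libraries to mice, and they do not say whether the sorted and the bulk libraries came from the same tumours. Values below are CPM as mean ± SD over 5 libraries unless stated otherwise, log2 fold changes carry their standard error (SE) where given, and "higher in 5 of 5" counts libraries labelled IL33KO against the WT median.

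Il33 (ENSMUSG00000024810.16, chromosome 19, 29925114 to 29960718, mm10) was counted in all 20 libraries, including every library labelled IL33KO. In sorted leukocytes it stood at 12.8 ± 5.56 CPM in the WT libraries (272 to 1084 counts) and 17.4 ± 4.61 CPM in the libraries labelled IL33KO (705 to 1123 counts). The log2 difference was +0.47 (SE 0.29, edgeR adjusted p = 0.524, higher than the WT median in 5 of 5 libraries). In bulk tumour it stood at 57.9 ± 5.16 CPM in WT (4001 to 4726 counts) and 46.5 ± 6.84 CPM in the libraries labelled IL33KO (3043 to 4452 counts). The log2 difference was −0.33 (SE 0.13, adjusted p = 0.724, lower in 5 of 5). A two-sided exact permutation test of log2 CPM gave p = 0.175 in sorted leukocytes and p = 0.0238 in bulk tumour. The smallest p that 5 against 5 libraries can give is 0.00794. Of the alternatives, limma voom with sample quality weights alone called Il33 in bulk tumour (log2 −0.43, adjusted p = 0.0176, range over alternatives 0.0176 to 1.00). Gene-level counts do not show which exons the reads came from, and the labels do not describe the deleted part of the gene, so Il33 counts do not check the genotype labels. The groups are called the libraries labelled IL33KO throughout. Il1rl1 (ENSMUSG00000026069.15, chromosome 1, 40429570 to 40465415), the receptor gene, was at 10.8 ± 4.92 against 11.3 ± 5.82 CPM in sorted leukocytes (log2 +0.07, SE 0.39, adjusted p = 0.963).

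**Figure D1:**
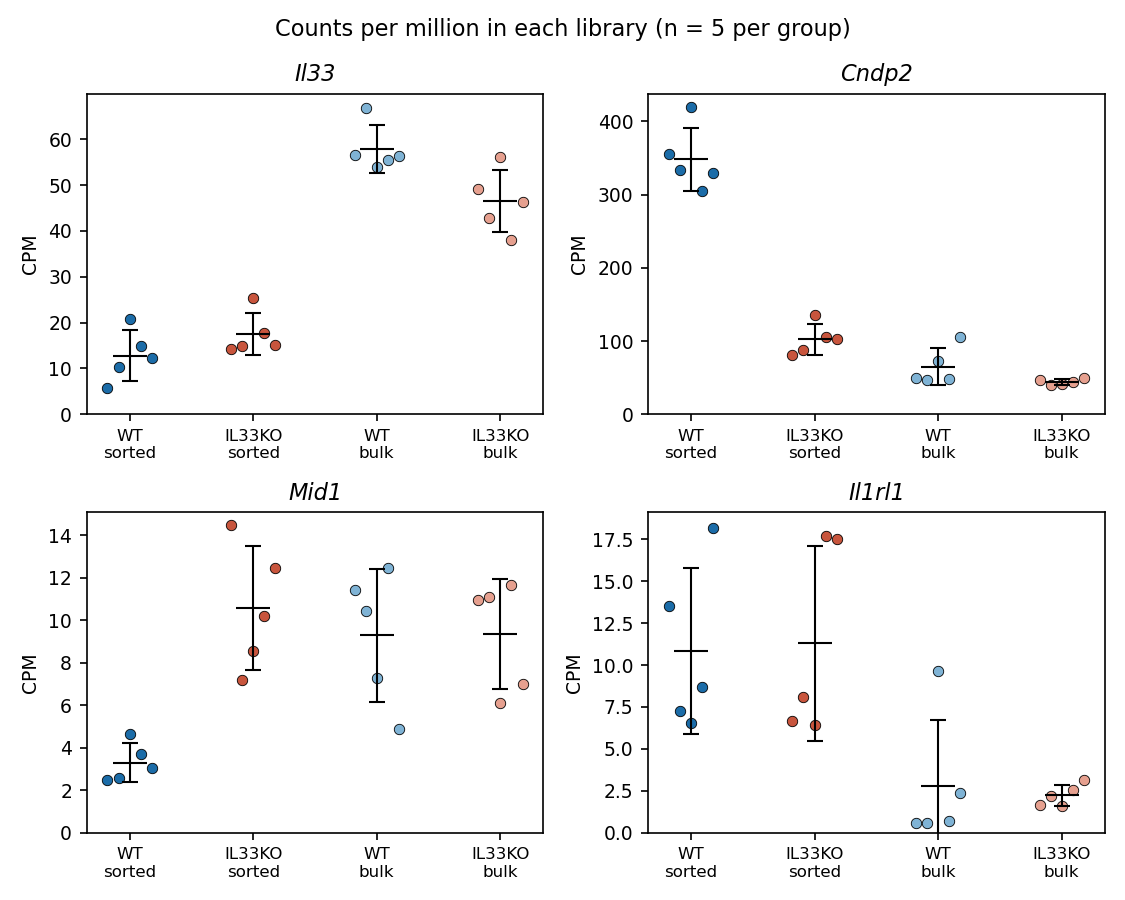
CPM of Il33, Cndp2, Mid1 and Il1rl1 in each library, with points for libraries and bars for the mean ± SD of the 5 libraries of a group. Cndp2 lay between 305 and 419 CPM in the sorted WT libraries and between 80.8 and 135 CPM in the sorted libraries labelled IL33KO, while Il33 was present in every group.

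The first comparison asked how the sorted leukocyte libraries labelled IL33KO differ from those labelled WT. Cndp2, which encodes a cytosolic dipeptidase (ENSMUSG00000024644.16, chromosome 18, 84667465 to 84685702), fell 3.36-fold, from 348 ± 43.5 CPM in WT to 102 CPM (80.8 to 135) in the sorted libraries labelled IL33KO (log2 −1.75, SE 0.14, adjusted p = 0.00185, lower in 5 of 5). Gm15446, a predicted protein-coding gene outside the rule for named genes and chosen after its values were seen (ENSMUSG00000090015.8, chromosome 5, 109923400 to 109943936), rose from 0.405 ± 0.141 to 3.38 ± 1.31 CPM (log2 +3.07, SE 0.37, adjusted p = 0.0428, higher in 5 of 5). Mid1, an X-linked ubiquitin ligase gene (ENSMUSG00000035299.16, chromosome X, 169685199 to 170005736), had the next smallest p without passing in edgeR, at 3.30 ± 0.906 against 10.6 ± 2.93 CPM (log2 +1.70, SE 0.23, adjusted p = 0.0706, higher in 5 of 5). The other genes named for the smallest p also did not pass in edgeR, and each differed by less than 1.5-fold. DESeq2 and limma voom with sample quality weights called Mid1 and all 8 of these genes in the same direction. Among those with positive values were Gabpb2 (log2 +0.48, adjusted p = 0.0768), Fam178a (+0.37, 0.0956), Eif2ak2, the double-stranded RNA-activated kinase PKR (+0.41, 0.144), and Nr2c2 (+0.40, 0.144). Those with negative values were Snx20 (log2 −0.53, adjusted p = 0.0706), the clathrin adaptor gene Ap2s1 (−0.51, 0.0768), the homeobox gene Hlx (−0.56, 0.0768) and Ndufaf3, an assembly factor of respiratory complex I (−0.44, 0.144). Each of these 8 genes lay on one side of the WT median in 5 of 5 libraries labelled IL33KO. They were chosen for small p values in the same libraries, so this adds no separate support.

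Genes of T cell, group 2 innate lymphoid cell and dendritic cell biology that had been fixed before the data were examined did not pass in sorted leukocytes. Ccl5, a T cell-attracting chemokine, was at 324 ± 111 against 245 ± 81.5 CPM (log2 −0.39, adjusted p = 0.608), Batf3, a transcription factor of cross-presenting dendritic cells, at 24.5 ± 3.76 against 18.6 ± 4.50 (−0.38, 0.385). Itgae, which encodes CD103, was at 98.7 ± 31.2 against 103 ± 31.1 (log2 +0.06, adjusted p = 0.945). Cd8a was at 201 ± 72.5 against 175 ± 87.3 CPM (log2 −0.20, adjusted p = 0.866), and Gzmb at 167 ± 119 against 119 ± 69.0 (−0.46, 0.809). Ifng (log2 −0.36, adjusted p = 0.711) and Foxp3 (+0.16, 0.866) did not pass either. The checkpoint genes Pdcd1 (log2 +0.09, adjusted p = 0.933) and Cd274 (−0.21, 0.712) and the type 2 genes Gata3 (+0.03, 0.982), Areg (−0.10, 0.852), Il13 (−0.16, 0.940) and Il5 (+0.19, 0.952, below 1 CPM in both groups) had adjusted p values above 0.7. In the list of group 2 innate lymphoid cell genes 0 of 13 tested members passed over all genes with edgeR. When adjusted over the list alone, 1 was lower: Crlf2, a subunit of the TSLP receptor, at 77.2 ± 17.2 against 43.4 ± 9.34 CPM (log2 −0.81, edgeR adjusted p = 0.149 over all genes). DESeq2 and voom called Crlf2 lower over all genes as well.

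Of the 16731 genes tested in sorted leukocytes, edgeR called 1 higher and 1 lower. At the same time 2156 genes had an unadjusted p under 0.05, where chance alone gives about 837. DESeq2 called 142 higher and 335 lower, and limma voom with sample quality weights called 186 higher and 207 lower. For 619 genes (3.70%) the 5 libraries labelled IL33KO did not overlap the 5 WT libraries, against 0.794% by chance. Leaving out any single library other than IL33KO 3 left only Cndp2 past the threshold (1 gene).

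All 14 tested macrophage genes had negative log2 fold changes in the sorted libraries labelled IL33KO (median −0.35). As a group they were called lower by camera with its preset correlation (adjusted p = 5.92e-07). They were not called with an estimated correlation (adjusted p = 0.812), by fry (0.272) or by the exact permutation test of the list score (0.155). Before adjustment the exact p was 0.00794, the smallest that the design allows. Only 2 of 39 lists had it, and at that number adjustment keeps the exact test from passing any list. None of the 14 genes passed over all genes with edgeR, and 6 were lower when adjusted over the list alone. Among these were Trem2 (179 ± 10.6 against 117 ± 19.3 CPM, log2 −0.61), and the complement genes C1qc (2112 ± 196 against 1438 ± 265, −0.54) and C1qa (−0.49). Replicate 1 of the libraries labelled IL33KO stood apart in this list, with a macrophage score of 8.23 against 8.72 to 8.81 in the other 4. The WT libraries lay at 8.85 to 9.15, and without that replicate camera with the preset correlation still called macrophages lower (adjusted p = 8.43e-06, range over alternatives 1.08e-08 to 0.812). Oxidative phosphorylation genes were negative in 14 of 15 members (median log2 −0.15), with 3 lower when adjusted over the list alone, namely Cox6a1 (−0.41), Cox5a (−0.40) and Sdhb (−0.30). The list was called lower (adjusted p = 6.73e-05), and not with an estimated correlation (adjusted p = 0.797). MHC class I presentation genes were negative in 9 of 11 members (median −0.26), with 7 lower when adjusted over the list alone. Among them were the immunoproteasome genes Psmb10 (−0.37) and Psmb9 (−0.25) and the peptide transporter gene Tap2 (−0.35). This list too was called lower (adjusted p = 6.73e-05; adjusted p = 0.812 with an estimated correlation).

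Immediate early and stress-response genes were negative in 11 of 14 members, for example Junb (2372 ± 184 against 1482 ± 470 CPM, log2 −0.67), Ier3 (−0.52) and Zfp36 (−0.54), with 0 passing in edgeR over all genes or over the list alone. Camera called the list lower (adjusted p = 0.000601; adjusted p = 0.812 with an estimated correlation). Inflammatory cytokine genes were negative in 14 of 16 members, with 1 lower when adjusted over the list alone, Tgfb1 (−0.31). Tnf was at 113 ± 21.1 against 67.4 ± 31.2 CPM (−0.73) and Il1b at 3494 ± 810 against 2337 ± 649 (−0.57). That list was called lower (adjusted p = 0.00332; adjusted p = 0.846 with an estimated correlation). So was the chemokine list, negative in 21 of 29 members with 0 lower over the list alone in edgeR, for example Ccl8 (−0.57), Ccl4 (−0.56) and Cxcl16 (−0.30) (adjusted p = 0.00463; adjusted p = 0.812 with an estimated correlation). These 6 of 39 lists were all those called. Fry (lowest adjusted p = 0.0773) and an exact permutation test of list scores (lowest adjusted p = 0.155) called 0 of them. Macrophages and oxidative phosphorylation reached the smallest exact p that the design allows, 0.00794 before adjustment. With only these 2 of 39 lists at that p it could not pass after adjustment, so the exact test decides nothing for them. Leaving out WT 3 and IL33KO 3 together, which stood apart on the first principal component, left 3 of the 6 calls: macrophages, oxidative phosphorylation and immediate early genes. Leaving out 1 library moved the number of called lists from 6 to 12 (WT 4), 11 (IL33KO 3), 13 (IL33KO 4) or 10 (IL33KO 5).

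Transcripts of pancreatic acinar cells were present in the sorted libraries and varied between them. Cpa1, a digestive carboxypeptidase, was at 63.4 to 469 CPM in WT and at 94.4 to 5925 CPM in the libraries labelled IL33KO, where replicate 3 held the highest value. All 21 acinar genes had positive log2 fold changes (median +2.09), and 0 passed in edgeR over all genes or over the list alone (camera adjusted p = 0.156). The pan-leukocyte list, at a mean log2 CPM of 9.75 ± 0.158 in WT and 9.64 ± 0.139 in the libraries labelled IL33KO, had a median log2 fold change of −0.08 (camera adjusted p = 0.138), and tumour epithelium genes one of +0.14 (adjusted p = 0.231).

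In bulk tumour edgeR called 0 genes, and the 10 genes named for the smallest p were called by DESeq2 and by limma voom with sample quality weights. Cxcr2, the receptor for neutrophil-attracting chemokines, was at 17.7 ± 2.39 CPM in WT and 9.36 ± 1.34 CPM in the libraries labelled IL33KO (log2 −0.94, SE 0.14, edgeR adjusted p = 0.724, lower in 5 of 5; range over alternatives 1.55e-05 to 0.988). Csf3r, the receptor for granulocyte colony-stimulating factor, was at 45.4 ± 3.26 against 30.4 ± 5.07 CPM (log2 −0.60), and Cxcl5 at 156 against 104 (−0.59). Duoxa2 was at 41.9 ± 8.18 against 21.2 ± 7.09 (−1.01) and Sectm1b at 13.6 ± 4.37 against 5.43 ± 1.87 (−1.35), each lower in 5 of 5. On the higher side were Ncam1 (log2 +0.44), Cdon (+0.52), Itih5 (+1.05), Dpysl2 (+0.33) and Prss23 (+0.53), each higher in 5 of 5, and all 10 genes had an edgeR adjusted p of 0.724. Since they were chosen for small p values in these libraries, the counts of 5 of 5 add no separate support. Of 17258 genes edgeR called 0, with 1098 at an unadjusted p under 0.05 (863 by chance). DESeq2 called 22 higher and 31 lower, and limma voom with sample quality weights called 1916 higher and 1448 lower. The 2 groups did not overlap for 116 genes (0.672%, against 0.794% by chance). Leaving out WT 5 gave 19 called genes in edgeR in place of 0.

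The genes fixed beforehand did not pass in edgeR in bulk tumour either: Ccl5 (32.2 ± 24.7 against 40.1 ± 17.7 CPM, log2 +0.29), Cd8a (+0.04), Itgae (+0.01), Batf3 (+0.56), Gzmb (+0.04), Ifng (+0.23), Foxp3 (+0.16), Pdcd1 (+0.16), Cd274 (+0.15), Gata3 (+0.50), Areg (+0.02) and Il13 (+1.13, below 1 CPM in both groups) had adjusted p values from 0.724 to 0.995. Limma voom with sample quality weights, alone among the alternatives, called Batf3 (log2 +1.15), Ccl5 (+1.08), Ifng (+1.09), Gzmb (+1.66) and Cd274 (+0.61) higher. Its adjusted p for these genes was 0.0127 to 0.0303, and the range over all alternatives was 0.0127 to 1.00. Il1rl1 was at 2.78 ± 3.92 CPM in WT, where replicate 3 held 9.66 CPM, and at 2.23 ± 0.635 CPM in the libraries labelled IL33KO (log2 −0.33, adjusted p = 0.881). With limma voom and sample quality weights Il1rl1 changed sign and was called higher (log2 +1.52, adjusted p = 0.0398). Il5 was too low to be tested in bulk tumour.

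Fibroblast genes had the smallest list p in bulk tumour, with positive log2 fold changes in all 14 members (median +0.90). Examples are Col3a1 (431 ± 146 against 826 ± 331 CPM, log2 +0.91), Col1a2 (+0.96), Col5a1 (+0.89) and Lum (+1.15). None passed in edgeR over all genes or over the list alone. The camera call (adjusted p = 1.78e-07) was lost with an estimated correlation (adjusted p = 0.595). Mesothelium genes were positive in 7 of 7 members (median +1.78). When adjusted over the list alone, 4 were higher: Muc16 (log2 +2.33), Gpm6a (+2.13), Upk3b (5.30 ± 2.85 against 22.4 ± 17.7 CPM, +2.05) and Upk1b (+1.78). Type 2 response genes were positive in 11 of 12 members, for example Retnla (4.17 ± 4.15 against 14.9 ± 4.36 CPM, +1.82), Ccl17 (+1.04) and Ccl22 (+0.55), with 0 higher over the list alone in edgeR. Camera called both lists higher (adjusted p = 2.49e-05 and 1.78e-05; adjusted p = 0.595 for both with an estimated correlation).

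Lists of leukocyte types were also higher in bulk tumour by camera. All members were positive for mature dendritic cells (10 members, median log2 +0.52, adjusted p = 0.000233), macrophages (14, +0.26, 0.000289), conventional type 2 dendritic cells (9, +0.49, 0.000589), B cells (11 members, 0.00136), regulatory T cells (12, +0.44, 0.00238), the pan-leukocyte list (10, +0.25, 0.0225) and T cells (14, +0.17, 0.0479). With an estimated correlation the adjusted p of these lists was 0.595 to 0.622. The WT libraries were divided. B cell scores (mean log2 CPM) were −1.11, −0.989 and −1.06 in WT 1, 2 and 4, and 2.68 and 1.93 in WT 3 and 5. The libraries labelled IL33KO lay at 0.453 to 4.10, a range that held WT 3 and 5. With the pan-leukocyte score as a covariate 13 lists were called in place of 23, and T cells turned to a call lower. Natural killer cells (10 of 11 positive, adjusted p = 0.0159), eosinophils (8 of 9, 0.0113), group 2 innate lymphoid cells (8 of 10, 0.0279) and immune checkpoints (11 of 12, 0.0482) were called higher too, and lost with an estimated correlation (adjusted p = 0.595 to 0.622). Within the eosinophil list 1 gene, the ribonuclease gene Ear2, was higher when adjusted over the list alone (log2 +0.63), while Siglecf, a surface marker of eosinophils, had a log2 fold change of −0.61. Proliferation genes (14 of 15 positive, adjusted p = 0.00290), endothelium (12 of 12, 0.00624), red blood cells (8 of 8, 0.0253), chemokines (23 of 29, 0.0270), lymphoid tissue stroma (5 of 6, 0.0479) and immediate early genes (10 of 14, 0.0482) completed the 20 lists called higher, again with adjusted p values of 0.595 to 0.622 with an estimated correlation.

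Called lower in bulk tumour were neutrophils (adjusted p = 0.0186), hypoxia and glycolysis (10 of 13 negative, 0.0482) and the genes near Il33 on its chromosome (14 of 18 negative, 0.0492), each with an adjusted p of 0.595 with an estimated correlation. In the neutrophil list Cxcr2 and Csf3r were the 2 genes lower when adjusted over the list alone, and Camp had a log2 fold change of +1.31. The list median was +0.12, opposite in sign to its camera call. In the chemokine list, called higher, 2 genes were lower when adjusted over the list alone, Cxcl5 and Ccl20 (log2 −0.80). Tumour epithelium genes were not called (6 of 13 positive, adjusted p = 0.134). Muc1 (log2 −0.67) and Elf3 (−0.46) had the smallest p of that list. Camera thus called 23 of 40 lists, and the camera test with estimated correlation, fry (lowest adjusted p = 0.392) and the exact permutation test of list scores (lowest adjusted p = 0.547) called 0. Leaving out 1 library gave 14 to 31 lists. The number fell most, to 14, without WT 2 or IL33KO 5, and to 15 without WT 1 or IL33KO 4. It rose most, to 31, without IL33KO 3, and to 27 without WT 5.

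Muscle and acinar transcripts differed between single bulk libraries. Acta1, skeletal muscle actin, was at 532 CPM in WT 5, 1019 CPM in IL33KO 1 and 278 CPM in IL33KO 5 and at most 1.45 CPM in the other 7. Cpa1 was at 831 CPM in WT 5, 206 CPM in IL33KO 3 and 16.6 CPM in IL33KO 5 and at most 1.56 CPM in the other 7. The pan-leukocyte score was 5.75, 5.73, 6.58, 5.73 and 6.96 (mean log2 CPM) in WT 1 to 5 and 6.38, 6.39, 6.09, 6.51 and 7.06 in the libraries labelled IL33KO 1 to 5. The fibroblast score ranged from 4.78 to 5.92 in WT and from 5.37 to 6.54 in the libraries labelled IL33KO, and the mesothelium score from 1.61 to 3.07 and from 2.25 to 4.69.

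**Figure D2:**
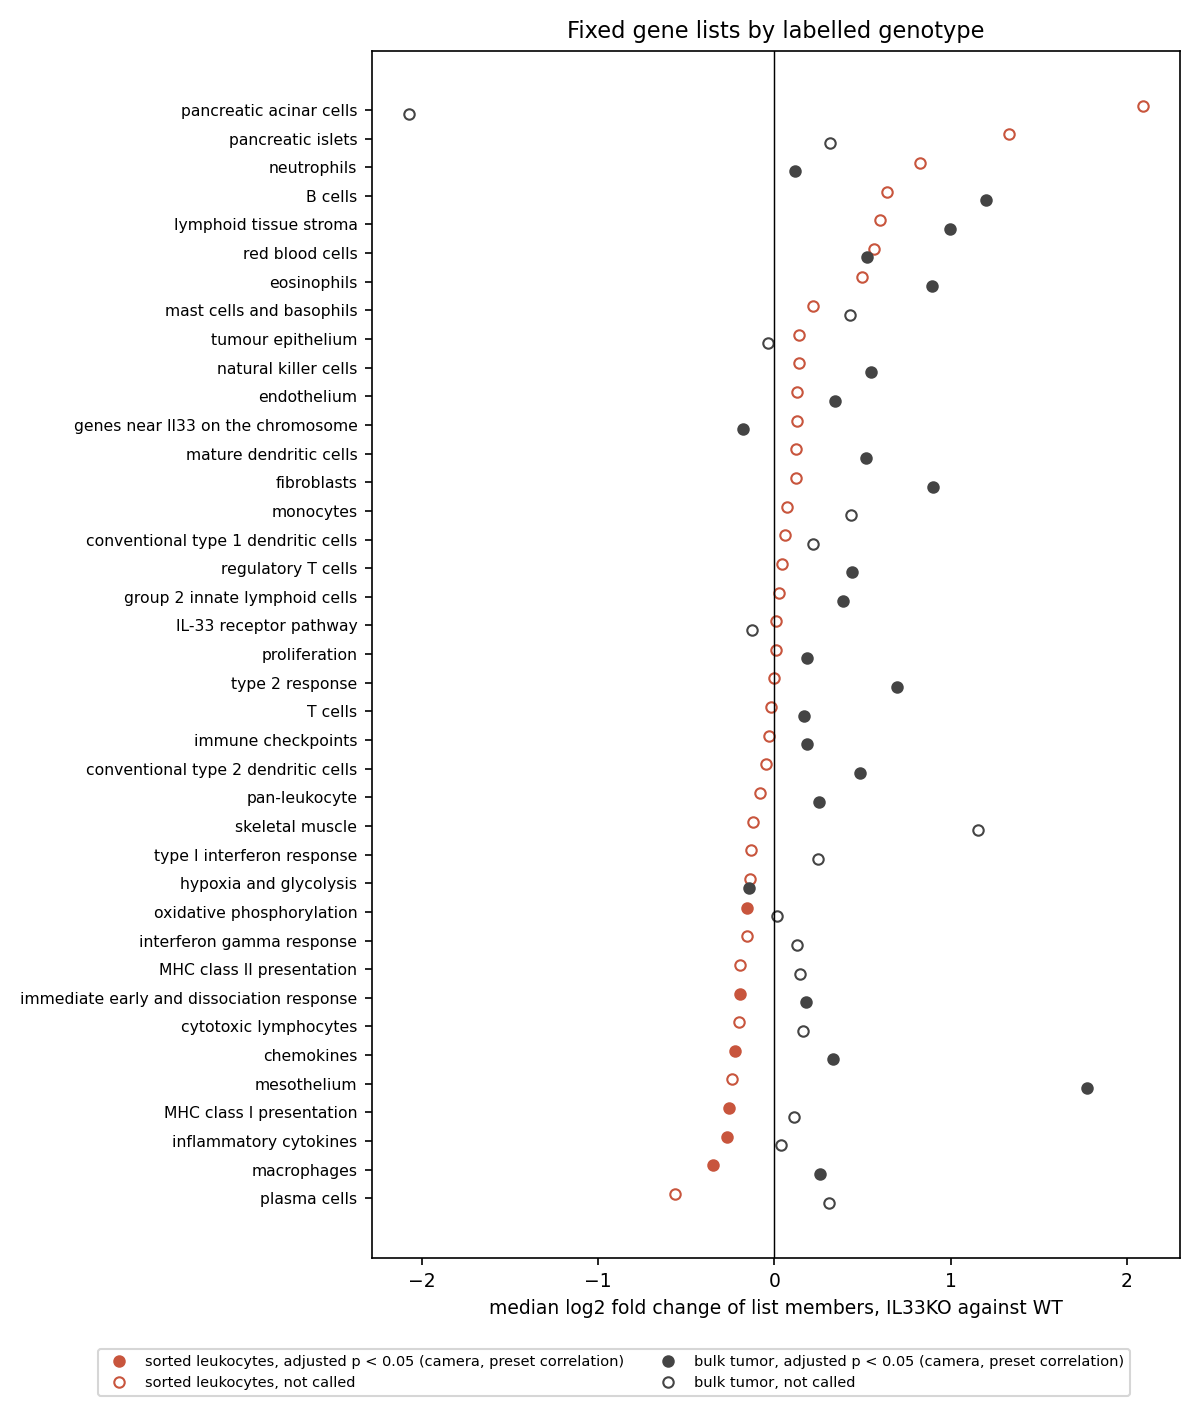
Median log2 fold change of each gene list, libraries labelled IL33KO against WT, in sorted leukocytes and in bulk tumour; filled points are lists called by camera with the preset correlation. Macrophages lie at −0.35 in sorted leukocytes and at +0.26 in bulk tumour, and none of the calls was made with an estimated correlation.

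Whether the genotype effect differed between sorted leukocytes and bulk tumour was tested as an interaction over all 20 libraries. Gm15446 had the smallest p and did not pass in edgeR (log2 +2.71, SE 0.41, adjusted p = 0.0526, range over alternatives 6.01e-07 to 0.497). It stood at 2.85 ± 0.750 CPM in bulk WT and 3.65 ± 0.497 CPM in the bulk libraries labelled IL33KO. The predicted gene Gm15784 (log2 +1.90), Dpysl2 (−0.64), Mid1 (+1.68) and Cndp2 (−1.21) followed, each with an edgeR adjusted p of 0.445. In bulk tumour Cndp2 was at 64.8 ± 25.4 CPM in WT and 44.4 ± 4.02 CPM in the libraries labelled IL33KO, and Mid1 at 9.29 ± 3.14 and 9.36 ± 2.59 CPM. The interaction was +0.78 (SE 0.33) for Il33 and +0.39 (SE 0.89) for Il1rl1, with adjusted p values of 0.445 and 0.877. edgeR called 0 of 18145 genes, with 2028 at an unadjusted p under 0.05 (907 by chance), and DESeq2 called 3 higher (Gm15446, Gm15784 and Mid1) and 1 lower (Dpysl2). Leaving out WT bulk 5 gave 27 called genes in edgeR, and DESeq2 size factors gave 1. Leaving out sorted WT 5 or sorted IL33KO 3 gave 1.

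Sorted leukocytes and bulk tumour were compared to show what the bead enrichment held. Leukocyte genes rose together in the sorted libraries: all 10 pan-leukocyte genes were higher (median log2 +3.33), such as Ptprc, which encodes CD45 (741 ± 104 against 75.0 ± 19.9 CPM, log2 +3.32, SE 0.15, adjusted p = 7.07e-13; n = 10 libraries each, edgeR), together with 14 of 14 macrophage genes (median +3.02) and 14 of 14 T cell genes (+2.91). So did 12 of 12 neutrophil genes (+4.31), 11 of 11 B cell genes (+4.10) and 12 of 13 group 2 innate lymphoid cell genes (+3.15). All 13 tumour epithelium genes fell (median −1.97), including Cdh1 (1065 ± 195 CPM in bulk, 268 ± 58.0 in sorted, log2 −1.97) and Krt18 (−1.96), and so did 12 of 14 fibroblast genes, such as Postn (−3.15) and Col5a1 (−2.16), and 6 of 7 mesothelium genes. Il33 fell by 1.78 on the log2 scale (52.2 ± 8.29 CPM in bulk, 15.1 ± 5.40 in sorted, SE 0.17, adjusted p = 1.38e-08), and Il1rl1 rose (2.50 ± 2.66 to 11.1 ± 5.09 CPM, log2 +2.17, SE 0.46, adjusted p = 0.000307).

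Among the genes that rose most in sorted leukocytes were immediate early and inflammatory genes: Fosb (log2 +7.39), Osm (+7.21), G0s2 (+7.05), Cxcl2 (+7.03), Zfp36 (+6.40), Ccrl2 (+6.27), Fos (34.2 ± 6.07 to 2332 ± 281 CPM, +6.11), Il1b (+6.05) and Nfkbid (+5.89), besides the steroid enzyme gene Hsd3b1 (+8.76, at a mean of 8.88 CPM with an SD above the mean). All 14 immediate early and dissociation-response genes rose (median +4.93). The protocol in the labels, which describes a single-cell suspension and bead selection, is the same for bulk and sorted samples. The genes that fell most were those of skeletal muscle: Mb (log2 −7.86), Acta1 (−7.63), Actn3 (−7.45), Tnnc2 (−7.04), Myl1 (−6.96), Tnnt3 (−6.71), Tcap (−6.55), Ldb3 (−6.47), Atp2a1 (−6.16) and Ckm (−5.66), and the Acta1 values show that its bulk mean came from 3 libraries. Without the 6 libraries that stood apart, 7 of these 10 genes turned to positive values, from +0.17 for Actn3 to +3.02 for Ckm, and with the replicate number as a block Atp2a1 and Ckm did.

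edgeR called 13684 of 18145 genes, 6788 higher and 6896 lower in sorted leukocytes, of which 3474 and 3715 differed by more than 2-fold; 2342 of the called genes are of kinds not named singly. Camera called 28 of 40 lists, 25 higher and 3 lower (tumour epithelium, fibroblasts and mesothelium), and 0 with an estimated correlation, where the lowest adjusted p was 0.347. The pan-leukocyte list, with all its members higher, was among those lost. A call lost with an estimated correlation therefore does not show that a list is unchanged.

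**Figure D3:**
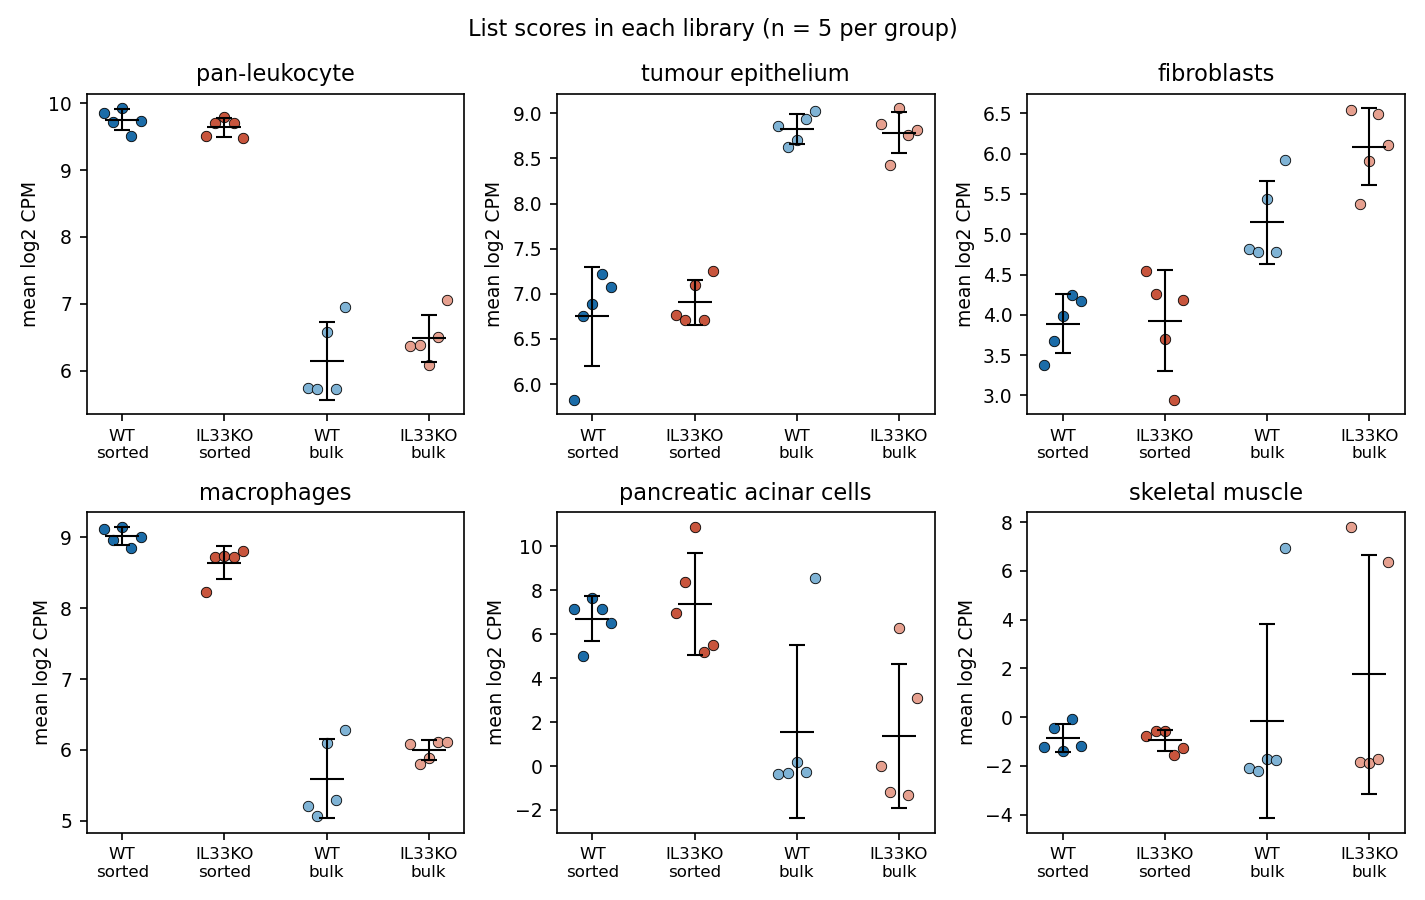
Mean log2 CPM of the members of 6 gene lists in each library (points) with the mean ± SD of the 5 libraries of a group. The pan-leukocyte score lay between 9.48 and 9.93 in sorted leukocytes and between 5.73 and 7.06 in bulk tumour, and 3 bulk libraries stood apart for skeletal muscle.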

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

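Values of single libraries were compared within each group of 5: a library stood apart where its gap to the nearest other library, as a share of the range of the group, exceeded 0.710. This held for 28 of 330 groups of values, where 16.5 are due by chance, since chance flags about 1 in 20 groups. Bulk WT 5 stood apart in 8 groups of values, bulk WT 3 in 5, and sorted IL33KO 1 and bulk IL33KO 3 in 3 each. Some of the tests below were chosen only after the result was seen. These were the regroupings with edgeR, voom and camera and the tests of dilution and of swapped labels. The tests of the chromosome of Il33 and of the source of Il33 were also chosen then. So were the bulk lists without 4 libraries or with the pan-leukocyte covariate, and the reading of the neighbours gene by gene. Camera with an estimated correlation was set before the results were seen, and only its reading as members moving together came afterwards.

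In bulk WT 5 the gap was 0.946 of the range for skeletal muscle genes (score 6.96, others −2.20 to −1.70), 0.942 for acinar genes (8.58, others −0.36 to 0.16), 0.891 for proliferation (6.20, others 5.59 to 5.65) and 0.788 for endothelium (4.32, others 3.31 to 3.52). Among its single genes it was 0.877 for Ccl17 (4.23 CPM, others 1.45 to 1.79), 0.778 for Gzmb, 0.743 for Itih5 and 0.711 for Gata3. Bulk WT 3 stood apart for adipocyte genes (0.900), mesothelium genes (0.836, score 3.07, others 1.61 to 1.85), Il1rl1 (0.802, 9.66 CPM, others 0.566 to 2.37), red blood cell genes (0.766) and Upk3b (0.763), and bulk WT 2 for Il33 (0.792, 66.9 CPM, others 54.0 to 56.7). Bulk IL33KO 3 was low in interferon gamma response genes (0.863, score 5.91, others 6.97 to 7.13), MHC class I (0.769) and MHC class II genes (0.759, score 6.38, others 7.55 to 7.92). Duoxa2 was high in bulk IL33KO 4 (0.784), and regulatory T cell genes in bulk IL33KO 5 (0.713).

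Among sorted libraries, WT 3 was high in proliferation genes (0.923, score 6.08, others 5.44 to 5.49), WT 5 low in Snx20 (0.771) and WT 1 low in Cox5a (0.730). IL33KO 1 was low in macrophage genes (0.837, score 8.23, others 8.72 to 8.81), high in Gabpb2 (0.864) and high in the sex-linked list (0.866), where Ddx3y had 9 counts. IL33KO 3 was high in Cpa1 (0.863, 5925 CPM, others 94.4 to 894) and in the genes near Il33 (0.717), and IL33KO 4 in Cd274 (0.764).

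Cndp2, Gm15446 and Mid1 separated the labelled genotypes in sorted leukocytes; dilution by tumour RNA would lower leukocyte genes together, and the pan-leukocyte list had a median log2 fold change of −0.0823. DNA carried along with the targeted locus would put such genes on the chromosome of Il33, and 0 of the 3 genes lie there. Stretches of other-strain DNA elsewhere would change neighbouring genes too; 13.4% of the tested genes within 5 Mb of the 3 genes had p under 0.05, against a median of 13.1% around sets of random genes, which does not decide. By gene the share was 28% for Cndp2 (7 of 25 neighbours), 16.7% for Mid1 (3 of 18) and 9.65% for Gm15446 (11 of 114), with no random sets matched to these numbers of neighbours. Such DNA, a difference in genetic background at the genes themselves and a response to the lack of IL-33 all stay open.

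Il33 was counted in every library labelled IL33KO. Within those libraries it was lower in sorted leukocytes than in bulk tumour (log2 −1.39, SE 0.24), while tumour epithelium genes had a median of −1.89 (−2.56 to −1.29) and fibroblast genes one of −2.42 (−3.30 to 0.03). This is consistent with Il33 RNA from cells other than leukocytes and does not tell implanted tumour cells, whose Il33 genotype the labels do not give, from host stroma. Swapped genotype labels would leave some libraries with 3 or fewer counts if deletion removed all counts, and 0 of 20 had so few, so that test cannot tell. A transcript from the targeted allele cannot be told from normal Il33 in gene-level counts.

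The third pattern was the number of gene lists called between the labelled genotypes in bulk tumour. With a correlation between list members estimated from the data, 0 of the 23 calls passed in the same direction. The same test called 0 of 40 lists in sorted against bulk, where all 10 pan-leukocyte genes were higher (median log2 +3.33). It can thus miss large shifts, so the loss of the calls does not decide whether members moved together between tumours. Without the 4 libraries that held acinar or skeletal muscle tissue (WT 5 and IL33KO 1, 3 and 5), 28 lists were called. Of the 23 calls, 18 passed in the same direction and 1 list turned. Only IL33KO 2 and 4 were then left against WT 1 to 4. Other splits of all bulk libraries gave a median of 15 list calls with camera, so the count of calls cannot tell whether such tissue underlies them. With the pan-leukocyte score as a covariate 13 lists were called, 8 higher and 5 lower, of which 10 were among the 23 in the same direction. T cells turned to a call lower and immune checkpoints turned without a call, while the loss of the pan-leukocyte list follows from the covariate itself and decides nothing; a different leukocyte share of the libraries may underlie part of the other calls.

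Regrouping the libraries asked how often other splits of the same samples gave as many calls. In sorted leukocytes 1 of 100 splits, the real one, gave as many genes with edgeR (2, highest other 1). With voom and quality weights 2 of 100 splits did (393, highest other 550), and with DESeq2 2 of 60 (477, highest other 598). These shares lie under 0.05, which makes chance less likely. They do not exclude it, since with voom and DESeq2 another split called more genes than the real one. For edgeR this rests on 2 genes against 1, and with the replicate block or without any 1 library save IL33KO 3 the real count was 1 as well. For bulk tumour chance cannot be excluded, since 19 of 100 splits gave as many genes with voom (3364; highest other 8464) and 17 of 60 with DESeq2 (53; highest other 4379). Nor can it for the gene lists, where 96 of 100 splits gave as many in sorted leukocytes (6; highest other 24) and 24 of 100 in bulk tumour (23; highest other 30). Where the real edgeR count was 0, in bulk tumour (highest other 2247) and for the interaction (highest other 1024), all 100 splits reach it whatever the data hold, so these splits decide nothing. Splits of bulk libraries that call many times more genes than the real one point to a structure of the samples other than the labelled genotype. For sorted against bulk 1 of 100 splits, the real one, reached 13684 genes (highest other 8753).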

How the results depend on the processing

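Cndp2 was called in 21 of 21 settings (log2 −1.87 to −1.63, adjusted p 1.99e-24 to 0.0193), Gm15446 in 10 of 20 (adjusted p 9.49e-14 to 0.280) and Mid1 in 4 of 21 (adjusted p 2.18e-09 to 0.323). The count of sorted genes, 2, became 477 with the DESeq2 Wald test, 393 with voom and quality weights, 19 with the pan-leukocyte covariate, and 1 with the strict filter, where Gm15446 was not tested; leaving out 1 library gave 1 to 3. The count of bulk genes, 0, became 53 with DESeq2 and 3364 with voom, and 0 to 19 with 1 library left out (19 without WT bulk 5). The interaction count, 0, became 1 with DESeq2 size factors and 4 with the DESeq2 test, and 0 to 27 with 1 library left out (27 without WT bulk 5). Sorted against bulk stayed within 1.5 times of 13684 in every setting run (13484 to 14058 with 1 library left out). The cause of these shifts was not tested. Simulated data had given DESeq2 40 unchanged genes among 186 calls in sorted leukocytes.

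Of the gene lists, 6 in sorted leukocytes and 23 in bulk tumour, 0 were called with an estimated correlation, 0 with fry and 0 by the exact permutation test. The smallest possible exact p, 0.00794, cannot pass adjustment over this many lists unless several lists reach it. Chosen after seeing the data, leaving out the libraries that stood apart gave 3 in sorted leukocytes, and the pan-leukocyte covariate 13 in bulk tumour. Leaving out 1 library gave 5 to 13 and 14 to 31. The replicate numbers were not taken to pair the samples, since not every same-numbered pair correlated over 0.1. Between genotypes 4 of 5 bulk pairs (−0.11 to 0.70) and 3 of 5 sorted pairs (−0.20 to 0.45) did, and between sorted and bulk 1 of 5 in each genotype (−0.36 to 0.33). In each pair of groups 1 or 2 of 5 libraries correlated best with their own number. With the replicate block, 1 sorted gene (Cndp2, without Gm15446 at log2 +3.00 and adjusted p = 0.163), 0 bulk genes, 0 interaction genes, 13241 genes in sorted against bulk, 6 sorted lists and 20 bulk lists were called.

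Il1rl1 in bulk tumour changed sign with voom and quality weights (log2 +1.52, adjusted p = 0.0398). In sorted against bulk, leaving out the 6 libraries that stood apart, 3 of which held the muscle transcripts, turned Acta1 (log2 +0.46), Actn3 (+0.17), Tnnc2 (+2.94), Tnnt3 (+1.92), Tcap (+0.35), Atp2a1 (+2.88), Ckm (+3.02) and Adipoq (+0.27), and the replicate block turned Atp2a1 (+0.0064) and Ckm (+0.34). These were the 1 value in bulk tumour and the 10 in sorted against bulk that reversed with a call in the main or the alternative fit, with 0 in sorted leukocytes. Among the named genes a further 106 values in bulk tumour and 79 in sorted leukocytes changed sign without a call in either fit. For example, Cd8a in bulk tumour ranged from log2 −0.37 to +0.44 over the settings. No setting moved the median log2 fold change of all genes by more than 0.04. At this depth and spread, edgeR recovered 68.7% of simulated 2-fold changes in sorted leukocytes and 64.2% in bulk tumour, among genes with a mean of at least 5 CPM. Simulated counts varied independently from gene to gene, without the tissue differences between real libraries, so these shares need not hold for the real data. Some observed differences above 2-fold did not pass, such as Mid1 in sorted leukocytes and Sectm1b and Muc16 in bulk tumour. Whether these are true changes is not known. By the simulated recovery, changes of 2-fold in single genes can be missed, and larger ones may be.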

Other observations

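In sorted leukocytes 33 further gene lists were not called, with camera adjusted p values from 0.124 to 0.989. B cell genes were positive in 11 of 11 members (median log2 +0.64, adjusted p = 0.323), plasma cell genes negative in 6 of 7 (−0.56, 0.158), eosinophil genes positive in 7 of 9 (+0.50, 0.231) and interferon gamma response genes negative in 12 of 15 (−0.16, 0.168). The B cell scores were divided: 6.78, 6.47, 5.95, 3.98 and 4.18 in the sorted libraries labelled IL33KO 1 to 5, against 4.37 to 5.87 in sorted WT. Genes of T cells (median −0.02), regulatory T cells (+0.04) and conventional type 1 dendritic cells (+0.06) had adjusted p values of 0.880 to 0.989. Of MHC class II genes 3 were lower when adjusted over the list alone, H2-Eb1 (log2 −0.37), H2-Ab1 (−0.37) and the invariant chain gene Cd74 (−0.33), as were Bst2 (−0.46) in the type I interferon list and Eng (−0.35) in the endothelium list, and 0 of these lists were called by camera (adjusted p = 0.150, 0.138 and 0.721). The median and the camera direction differed in sign for neutrophils (+0.83, adjusted p = 0.704), type 2 response, IL-33 receptor pathway, mast cells, proliferation and group 2 innate lymphoid cells.

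In bulk tumour 17 lists were not called. Monocyte genes came closest (median log2 +0.43, adjusted p = 0.0531), for example Ccr2 (13.5 against 24.9 CPM, +0.85), F13a1 (+0.80) and Vcan (+0.81). Skeletal muscle (+1.15, adjusted p = 0.123) and acinar genes (−2.08, 0.567) were not called either, and their values differed widely between single libraries. MHC class I genes (+0.11, 0.177) and interferon gamma response genes (+0.13, 0.162) were also not called. The median and the camera direction differed in sign for adipocytes (+0.16, adjusted p = 0.428) and oxidative phosphorylation (+0.01, adjusted p = 0.936).

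In sorted against bulk, all 9 genes of conventional type 2 dendritic cells, 13 of 13 cytotoxic lymphocyte genes, 12 of 12 immune checkpoint genes and 11 of 11 MHC class II genes were higher in sorted leukocytes, as were 11 of 12 regulatory T cell and 6 of 7 IL-33 receptor pathway genes, with Il33 itself lower. Endothelium genes divided, with Pecam1 (log2 +1.95) and Eng (+1.04) higher and 10 genes lower. Acinar genes were higher for 10 of 21 members over all genes and for 0 when adjusted over the list alone.

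A hypothesis was that passenger DNA around the targeted locus changes neighbours of Il33 in sorted leukocytes. Of the 53 tested genes within 5 Mb of Il33, 7 (13.2%) had p under 0.05, against a median of 12.5% (95th percentile 20.6%) around random genes, so the test, written down before this result was seen, cannot tell whether passenger DNA may act there. The fixed list of genes near Il33 was positive in 13 of 17 members in sorted leukocytes, with camera adjusted p = 0.130 and fry adjusted p = 0.359. Fry for changes of either sign gave an unadjusted p of 0.000194. In bulk tumour 14 of 18 members were negative. These list tests were not set up to test passenger DNA, so the question stays open.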
